A study of Homo sapiens with 9 samples.

How the data were processed

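RNA of HK-2 cells, an immortalised line from human kidney proximal tubule, was measured on 9 one-colour Agilent arrays. Per the labels, 3 arrays were controls, 3 had stearoyl lysophosphatidylcholine (LPC, 18 acyl carbons and 0 double bonds) at 30 µM and 3 had it at 60 µM, all for 24 h. The lipid was carried on fatty acid-free albumin, and controls received the albumin solution. The palmitoyl form that the series design also names was not analysed here. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

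Per the file headers, the scanner files came from Feature Extraction 12.1.1.1 with protocol GE1_1200_Jun14 and array design 072363. Their processed signal is an intensity per the file headers: background-subtracted and detrended on each array, not scaled between arrays, with low values replaced by a small positive number. The median signal and local background median are also intensity values per the file headers, in pixel units and with no normalization. The deposited series table holds log2 values. Tested on the scanner files, each of its columns was the log2 processed signal minus 1 constant, the array's 75th percentile, with signals under 1 set to 1 first. Over 57901 probes with 1 spot no value then differed by more than 0.0058. Without that floor, which met 6692 to 7841 of these probes on an array, the difference had an SD of 0.033 to 0.040. The medians of its columns were -3.81, -3.76 and -3.85 for the controls, -3.88, -3.73 and -3.88 at 30 µM, and -3.77, -3.84 and -3.74 at 60 µM. The table was not centred by gene, so it carries no direction of its own, and how the authors computed it is not given in the sources used here.

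Of 62976 spots on an array, 2075 were control spots and were left out. The log2 processed signal of the remaining spots was scaled by subtracting the array's 75th percentile, spots carrying the scanner software's outlier flags were set to missing, and repeated spots of a probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group. Of 58201 probes, 31104 (53.4%) matched a gene symbol through their RefSeq accession, in a table for assembly GRCh38.p14, and the others kept the accession given in the files. No genome sequence was used, so no positions are given. The brightest tested probe stood for each gene, which left 25568 genes from 31504 probes, 16279 of them with a symbol and 9289 without.

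Each array had between 31285 and 32417 probes well above background (53.8% to 55.7%), 48 to 80 spots with outlier flags and 0 saturated spots. The number of arrays limits the precision. The median standard error of a log2 change was 0.09, over 6 residual and 2.02 prior degrees of freedom.

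The 3 groups were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The R package data.table, in version 1.17.8, read the files. The comparisons were 60 µM against control, 30 µM against control and 60 µM against 30 µM, with a moderated F test over all 3 groups. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 2-sided. With 3 arrays against 3, chance alone leaves the groups without overlap in 10% of genes. Changes are log2 differences with the standard error of the fit, n = 3 per group. Where a probe was well above background on 0 arrays of a group, the fold is a lower bound. It was computed with each dim array set to the lowest signal that any probe well above background had there, or to the probe's own signal if that was higher.

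Choices made before the data were examined were the groups, the tests, 28 gene lists with 473 genes (417 of them tested), the rule for named genes and most alternatives. The lists covered sterol, fatty acid and phospholipid metabolism, PPAR and LXR targets, lysophospholipid receptors, stress responses, inflammation, growth and death, tubule identity and injury, matrix, organelles, hypoxia and ribosomes. They also held markers of fibroblasts, endothelium, leukocytes and distal nephron, the other cell types a kidney sample can hold. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists of a comparison. An estimated correlation and fry stood beside it.

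Named genes have a symbol. For each dose against control, the rule took the 8 largest rises and the 8 largest falls among passed genes well above background on all 6 arrays and with groups that did not overlap. For 60 µM against 30 µM it took 5 and 5. It added the 2 largest lower bounds in each direction, up to 4 passed genes per list by the size of the 60 µM change, and 21 genes named in any case. This gave 141 genes, a few of which are not reported here though they stay in the counts and lists. Passed genes with several probes had the same sign on all of them in 84.9% of cases at 60 µM, 89.7% at 30 µM and 87.4% between the doses.

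Batches were read from the array positions. Slide 1 held the controls and 30 µM replicate 1 in its upper row, and 30 µM replicates 2 and 3 with 60 µM replicates 1 and 2 in its lower row. Slide 2, scanned separately, held 60 µM replicate 3 in its upper row. All 3 controls thus shared 1 slide row. Since slide 2 held a single array, the slide as a block gives the same fit as leaving out 60 µM replicate 3. It cannot adjust for a difference between the slides.

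The alternatives were other scalings (centring on the median of detected probes, quantile), the deposited table, outlier spots kept, other filters and probe rules, an intensity trend with robust spread, only the 2 groups compared, replicate number or slide as a block, a stricter threshold of 0.01, and each array left out. Background correction by normexp (offset 50), planned on the mean signal, was run on the median signal. That change, the slide row as a block and fits within 1 slide row were chosen after seeing the data.

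The procedure was tested on simulated data: 10 sets of 25568 genes with 200 changed genes each. The shares called hold for so few changed genes. Where many change, as where 9161 passed at 60 µM, the adjusted threshold is looser, so they are not the shares found there. Of genes changed by 0.5 on the log2 scale, 48.2% were called at 60 µM, 50.4% at 30 µM and 50.1% between the doses. For changes of 1 these shares were 85%, 86.2% and 87.3%, and for changes of 0.3 they were 8.21%, 9.25% and 5.97%. False calls made up 5.82%, 6.19% and 5.65% of calls. Camera called a list of 20 genes shifted by 0.2 in 10 of 10 sets, and an unshifted one in 0 of 10, at an unadjusted p under 0.05. The simulated genes were independent, so this does not show how often camera calls lists of correlated genes falsely. The arrays were also checked for duplicates. The log2 difference between 2 arrays had an SD of 0.24 to 0.30 within groups and 0.28 to 0.55 between groups, and no arrays were identical.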

Results

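Gene expression was measured on 9 arrays of HK-2 cells, 3 per group: controls and cells given stearoyl LPC, a phospholipid with a single fatty acid chain, at 30 µM or 60 µM for 24 h. Between 31285 and 32417 of 58201 probes on an array were well above background, and the 75th percentile of the processed signal lay between 147 and 154. Across genes, arrays of 1 group correlated at a mean r of 0.996 to 0.997. The first principal component held 60.9% of the variance and separated the 60 µM arrays, at 47.3 to 51.5, from the other 6, at -27.1 to -21.7. On the second, with 8.79%, the controls lay at 8.45 to 21.0 and the 30 µM arrays at -26.1 to -3.00. By the moderated F test, 9696 of 25568 genes differed among the groups.

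**Figure D1:**
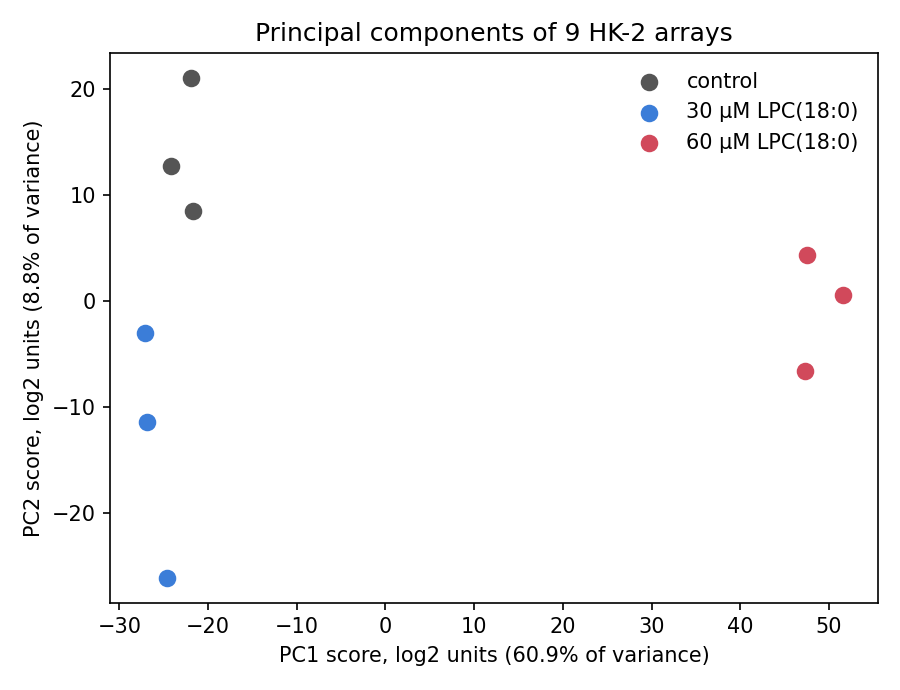
Scores of the 9 arrays on the first and second principal components, in log2 units, coloured by group, each point 1 array. The 60 µM arrays lie at 47.3 to 51.5 on the first axis, and the controls and 30 µM arrays at -27.1 to -21.7.

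The comparison of 60 µM with control asks what 24 h of the higher dose did to expression in these cells. Among genes above background on all 6 arrays, SCG5, a chaperone of a prohormone convertase, rose 48.3-fold (5.59 ± 0.13 on the log2 scale, SE, n = 3 per group). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 40.2-fold (5.33 ± 0.07), and SCEL, a precursor of the cornified envelope, 21.6-fold (4.43 ± 0.14). TMEM158 (3.96 ± 0.07), the adaptor SHC4 (3.51 ± 0.11), the transcription factor KLF2 (3.40 ± 0.09), the collagenase MMP1 (3.25 ± 0.10) and the pro-apoptotic HRK (3.20 ± 0.11) also rose. The vasoactive peptide endothelin 2, EDN2, had the largest fall (-4.69 ± 0.19), ahead of ANKRD2 (-3.91 ± 0.10), SEMA5B (-3.84 ± 0.22) and HOGA1, a mitochondrial enzyme of hydroxyproline breakdown (-3.47 ± 0.05). The natriuretic peptide gene NPPB (-3.19 ± 0.18), the sphingosine phosphate receptor S1PR1 (-2.98 ± 0.06), RAB7B (-2.95 ± 0.12) and the retinal reductase DHRS3 (-2.93 ± 0.15) fell as well. Each of these 16 genes had all 3 arrays at 60 µM beyond all 3 controls, as the rule for named genes required, with adjusted p between 3.78e-08 and 7.62e-06. The sizes depend on the background correction. With normexp, whose offset of 50 compresses changes of dim genes, the folds were 5.69 for SCG5, 6.26 for SCEL and 29.1 for ANGPTL4. The log2 changes were 1.57 for SHC4, 1.37 for HRK, -1.44 for ANKRD2 and -0.79 for RAB7B. Over all alternatives the smallest falls were -1.41 for SEMA5B, -1.27 for S1PR1 and -1.49 for DHRS3. HOGA1 stayed at -2.51 or lower, so its order with ANKRD2 and SEMA5B depends on the processing. Where 1 group was not above background the fold is a lower bound: the trypsin inhibitor SPINK1 was at least 10.1-fold higher, KISS1R at least 7.79-fold higher, CAVIN2 at least 3.97-fold lower and the bile acid conjugating enzyme BAAT at least 3.03-fold lower.

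In all, 9161 of 25568 genes passed (35.8%), 4079 higher and 5082 lower, and 1017 of them changed at least 2-fold, 544 higher and 473 lower. The median size of a passed change was 0.41, and in 50.6% of all genes the groups did not overlap, against 10% by chance. On slide 1 no row held both controls and 60 µM arrays, so no comparison within a row could be made. With the slide row as a block 2522 genes passed. With the slide as a block, the same fit as without 60 µM replicate 3, 8049 passed. The row block ties the 60 µM arrays to the controls through 30 µM replicate 1 alone, the only treated array in the controls' row, and 60 µM replicate 3, alone in its row, adds nothing to it. So estimated, the median passed gene kept 97.5% of its change and 9136 of the 9161 their sign, while the median standard error went from 0.09 to 0.15. The arrays behind this estimate also helped to call these genes, so the kept sign and size add no independent support.

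Genes of low oxygen and sugar breakdown shifted together at 60 µM. Of 18 measured members of the hypoxia and glycolysis list 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.97 (adjusted p = 1.21e-11, and adjusted p = 0.256 with an estimated correlation). Carbonic anhydrase CA9 rose by 2.42 ± 0.19 (0.58 with normexp), the angiogenic factor VEGFA by 2.01 ± 0.12, NDRG1 by 1.98 ± 0.13 and adrenomedullin, ADM, by 1.82 ± 0.09. For mitochondrial oxidative phosphorylation, 10 of 20 genes fell and 0 rose (13 and 0 adjusted over the list alone). The median was -0.17 (adjusted p = 0.000669, and adjusted p = 0.318 with an estimated correlation). Its largest falls were UQCRC2 (-0.39 ± 0.05), COX7C (-0.36 ± 0.04), ATP5F1A (-0.34 ± 0.05) and ATP5F1B (-0.33 ± 0.06).

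Oxidant defence and stress genes were also higher. The NRF2 antioxidant list had 14 of 18 genes up and 1 down (15 and 1 adjusted over the list alone). The median was 0.64 (adjusted p = 1.72e-08, and adjusted p = 0.101 with an estimated correlation), or 0.58 with the member that was dim in controls at its lower bound. Heme oxygenase HMOX1 rose by 2.25 ± 0.10, thioredoxin reductase TXNRD1 by 1.99 ± 0.10, sulfiredoxin SRXN1 by 1.04 ± 0.07 and OSGIN1 by 1.02 ± 0.06. In the ATF4 integrated stress response list 14 of 22 rose and 4 fell, the same counts adjusted over the list alone. The median was 0.32 (adjusted p = 0.00135, and adjusted p = 0.452 with an estimated correlation). PPP1R15A, a phosphatase subunit that restores translation, rose by 1.73 ± 0.08, CEBPB by 0.99 ± 0.05, the amino acid transporter SLC7A5 by 0.96 ± 0.15 and TRIB3 by 0.95 ± 0.09, while the lipoprotein receptor VLDLR fell (-1.09 ± 0.05). DDIT3 (0.47 ± 0.06), CHAC1 (0.39 ± 0.09) and ATF3 (0.62 ± 0.05) rose too, though probes of ATF3 ranged from -0.01 to 0.79.

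Smaller shifts went with protein folding. Among ER chaperones 6 of 20 rose and 1 fell, the same adjusted over the list alone. The median was 0.07 (adjusted p = 0.0203, and adjusted p = 0.318 with an estimated correlation). Members included EDEM1 at 0.91 ± 0.09, CRELD2 at 0.39 ± 0.07, MANF at 0.37 ± 0.06 and the chaperone BiP, HSPA5, at 0.33 ± 0.06. Heat shock genes had 6 of 14 up and 1 down (9 and 2 adjusted over the list alone). The median was 0.15 (adjusted p = 0.0112, and adjusted p = 0.452 with an estimated correlation). HSPA1A (0.71 ± 0.06) and HSPA1B (0.68 ± 0.05) are near-identical copies that their probes may not separate, CRYAB rose by 0.44 ± 0.06, and probes of HSPA6 (0.47 ± 0.12) ranged from 0.47 to 1.21. Immediate early genes, switched on fast by many signals, had 10 of 14 up and 2 down, also adjusted over the list alone. The median was 0.50 (adjusted p = 8.54e-05, and adjusted p = 0.256 with an estimated correlation). Members that rose included FOSB (1.60 ± 0.11), FOSL1 (1.28 ± 0.06) and KLF4 (1.23 ± 0.30) beside KLF2. In the list for autophagy and lysosome 11 of 23 rose and 2 fell, also adjusted over the list alone. The median was 0.15 (adjusted p = 0.00135, and adjusted p = 0.256 with an estimated correlation). Members included the cholesterol exporter NPC1 at 0.99 ± 0.05, MAP1LC3B at 0.93 ± 0.06, SQSTM1 at 0.73 ± 0.08 and the protease CTSD at 0.70 ± 0.06.

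Lipid genes were mixed at this dose. In cholesterol synthesis and uptake 11 of 24 rose and 3 fell (13 and 3 adjusted over the list alone). The median was 0.18 (adjusted p = 0.00233, and adjusted p = 0.452 with an estimated correlation). MSMO1 (0.51 ± 0.05), IDI1 (0.50 ± 0.07), INSIG1, which retains the sterol sensor in the ER (0.45 ± 0.07), and HMGCS1 (0.34 ± 0.05) rose. The sterol reductase TM7SF2 fell (-0.52 ± 0.05). Of 22 genes for phosphatidylcholine synthesis and LPC turnover, 10 rose and 1 fell, also adjusted over the list alone. The median was 0.12 (adjusted p = 0.0116, and adjusted p = 0.318 with an estimated correlation). The LPC transporter MFSD2A (0.98 ± 0.05) and the LPC acyltransferases LPCAT1 (0.81 ± 0.13) and MBOAT2 (0.75 ± 0.07) rose, and GDPD1, a lysophospholipase D, fell (-1.01 ± 0.20). With the slide row as a block the cholesterol list lost its call (median 0.08, adjusted p = 0.0559), as did phosphatidylcholine (median 0.13, adjusted p = 0.0565), ER chaperones (median 0.06, adjusted p = 0.0737) and heat shock (median 0.11, adjusted p = 0.0884), whose medians moved less.

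Other lipid lists did not pass at 60 µM. PPAR targets and fatty acid oxidation had 6 of 17 up and 6 down (7 and 6 adjusted over the list alone). The median was 0.11 (adjusted p = 0.322, and adjusted p = 0.483 with an estimated correlation). Even so, the lipid droplet coat PLIN2 rose by 2.20 ± 0.06, the carnitine transferase CPT1A by 1.92 ± 0.12 and the kinase PDK4 by 1.38 ± 0.11. Fatty acid synthesis had 6 of 16 up and 1 down, also adjusted over the list alone. The median was 0.03 (adjusted p = 0.293, and adjusted p = 0.691 with an estimated correlation). There HSD17B12 (0.53 ± 0.04), ELOVL6 (0.42 ± 0.08) and ME1 (0.39 ± 0.07) rose, the regulator SREBF1 fell (-0.41 ± 0.05), and SCD stood at 0.09 ± 0.07 (adjusted p = 0.343). The LXR list had 2 of 9 up and 3 down, also adjusted over the list alone (median 0.02, mean -0.05, tested as down, adjusted p = 0.935, and adjusted p = 0.936 with an estimated correlation). Members included the cholesterol exporter ABCA1 at 0.64 ± 0.08, MYLIP at -0.98 ± 0.08 and NR1H3 at -0.41 ± 0.05. Lysophospholipid receptors had 1 of 10 up and 2 down, S1PR1 and S1PR2 (-0.34 ± 0.06), also adjusted over the list alone (adjusted p = 0.708, and adjusted p = 0.724 with an estimated correlation).

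Matrix, interferon and metal-binding genes were lower at 60 µM. Of 18 genes in the list for TGF-beta response and matrix, 12 fell and 3 rose (13 and 4 adjusted over the list alone). The median was -0.67 (adjusted p = 0.000669, and adjusted p = 0.256 with an estimated correlation), or -0.32 with no filter on dim probes. The ligand TGFB2 (-2.54 ± 0.11), the actin binder TAGLN (-1.53 ± 0.06), thrombospondin THBS1 (-1.37 ± 0.05) and the repressor SNAI2 (-1.36 ± 0.12) fell most. Interferon-stimulated genes had 10 of 16 down and 0 up (11 and 0 adjusted over the list alone). The median was -0.35 (adjusted p = 0.00232, and adjusted p = 0.256 with an estimated correlation), or -0.21 with normexp. Members included RSAD2 at least 2.12-fold lower, IFIT1 at -1.05 ± 0.08 and OAS1 at -0.88 ± 0.12. Of 11 metallothionein list genes 10 fell and 0 rose, also adjusted over the list alone. The median was -0.39 (adjusted p = 3.05e-05, and adjusted p = 0.275 with an estimated correlation). MT1G (-1.59 ± 0.11), MT1F (-1.02 ± 0.04), MT1M (-0.82 ± 0.09) and MT1H, at least 1.51-fold lower, are close paralogs that the probes may not separate. Cytosolic ribosomal proteins had 4 of 18 down and 0 up, also adjusted over the list alone. The median was -0.12 (adjusted p = 0.00925, and adjusted p = 0.452 with an estimated correlation): RPS3 (-0.20 ± 0.05), RPL8 (-0.17 ± 0.05), RPL3 (-0.16 ± 0.04) and RPL10A (-0.15 ± 0.04). That list lost its call with quantile scaling (median -0.07, adjusted p = 0.220). Its share of falls was also near that of all tested genes, of which 5082 of 25568 fell.

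Inflammation, growth, death and tubule lists went both ways and did not pass. Among NF-kB cytokines 5 of 16 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.895, and adjusted p = 0.936 with an estimated correlation). The growth factor CSF2 rose by 2.59 ± 0.06 and IL6 by 0.59 ± 0.08. CXCL3 (-1.22 ± 0.13), CXCL5 (-0.78 ± 0.08) and CCL2, at least 1.48-fold lower, fell. CXCL8 was at -0.28 ± 0.11 (adjusted p = 0.0913). Of p53 targets 5 of 15 rose and 4 fell, also adjusted over the list alone (median 0.07, adjusted p = 0.254, and adjusted p = 0.698 with an estimated correlation). Members included the cell cycle inhibitor CDKN1A up by 1.56 ± 0.08, GDF15 by 1.07 ± 0.09, PLK3 by 0.97 ± 0.06 and the death receptor FAS by 0.72 ± 0.06. Apoptosis regulators had 4 of 16 up and 6 down, also adjusted over the list alone (adjusted p = 0.790, and adjusted p = 0.908 with an estimated correlation). Besides HRK, PMAIP1 (0.75 ± 0.06) and the caspase inhibitor XIAP (0.66 ± 0.05) rose and BCL2 fell (-1.0 ± 0.09). Cell cycle genes had 7 of 23 up and 6 down (7 and 7 adjusted over the list alone, adjusted p = 0.790, and adjusted p = 0.936 with an estimated correlation). Members included RRM2 (0.84 ± 0.05), AURKB (0.50 ± 0.07) and the proliferation marker MKI67 (0.34 ± 0.05) up and the replication helicase subunits MCM6 (-0.64 ± 0.05) and MCM5 (-0.48 ± 0.07) down.

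Proximal tubule differentiation genes had 3 of 11 up and 5 down at 60 µM, also adjusted over the list alone (median -0.02, mean 0.06, tested as up, adjusted p = 0.896, and adjusted p = 0.936 with an estimated correlation). SLC3A1, a cystine transporter subunit, rose by 0.49 ± 0.05 and the alkaline phosphatase ALPL fell (-0.54 ± 0.16). AQP1 was at 1.44 ± 0.16 with probes from -0.04 to 1.44. Tubular injury markers had 3 of 12 up and 4 down, also adjusted over the list alone (median -0.02, mean -0.05, tested as up, adjusted p = 0.973, and adjusted p = 0.986 with an estimated correlation). LCN2, or NGAL (-1.80 ± 0.14), KRT7 (-0.72 ± 0.08) and HAVCR1, or KIM-1 (-0.53 ± 0.06), fell, and CD44 rose by 1.77 ± 0.06, with probes from 0.85 to 1.77. Markers of other cell types were mostly not detected. Of 3 measured fibroblast genes LUM fell (-0.45 ± 0.05), and of 4 leukocyte genes CD14 fell (-0.34 ± 0.09), each also adjusted over the list alone. These lists had adjusted p of 0.790 and 0.777. None of 4 endothelial genes (adjusted p = 0.790) or 3 distal nephron genes (adjusted p = 0.895) passed.

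At 60 µM, limma with 1 array left out gave 7233 to 9225 genes, and 125 of the 134 named genes that passed did so in all 9 such fits. The others included TRPM2, HSPA6, ALPL, RPS3, RPL8, RPL3, RPL10A and CD14. With the slide row as a block 37 named results lost their call, INSIG1, HMGCS1, IDI1, SLC7A5, CHAC1, HSPA5, LPCAT1, AQP1, OAS1, RSAD2, CXCL3 and CXCL5 among them. With background correction by normexp, 7 named results lost theirs at the 75th percentile and 8 with quantile scaling. Among these were GDPD1, HSPA6, CCL2 and ALPL, all dim.

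**Figure D2:**
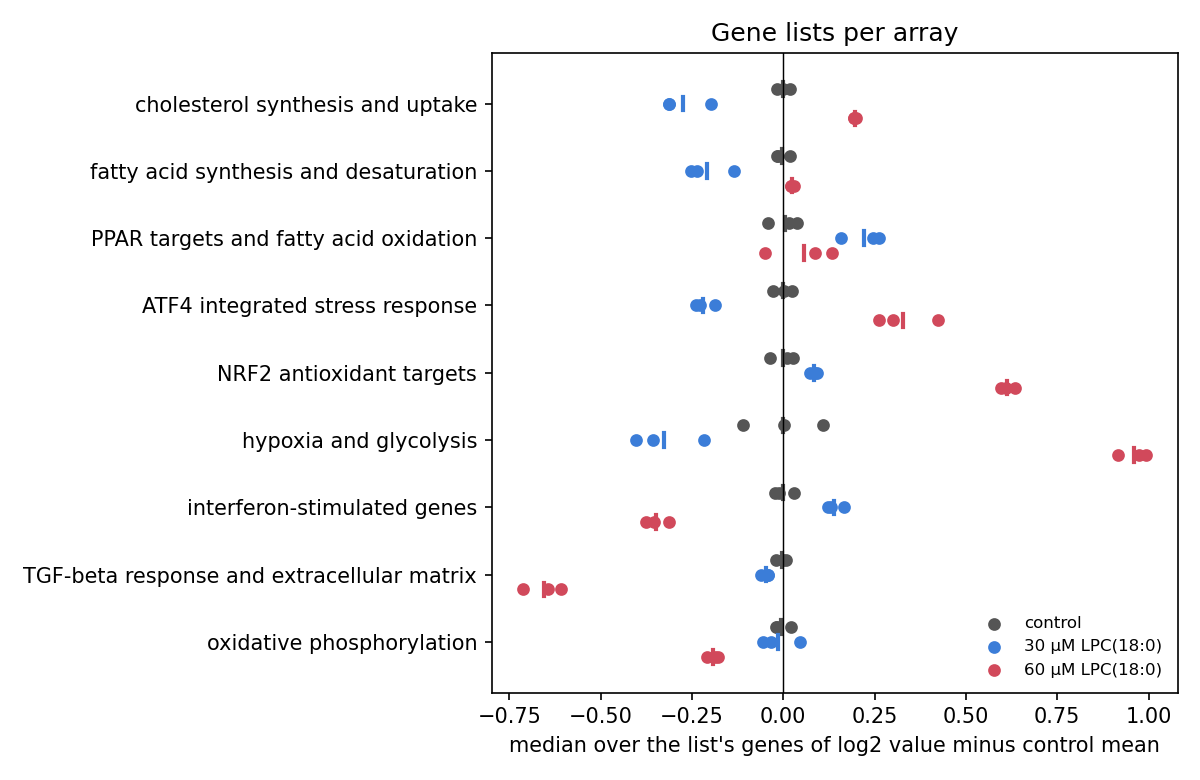
Median over each list's genes of the log2 value minus the control mean (horizontal axis, log2 units) for 9 of the lists, each point 1 array and each bar the mean of a group's 3 arrays. For hypoxia and glycolysis the 60 µM arrays lie at 0.92 to 0.99, the controls at -0.11 to 0.11 and the 30 µM arrays at -0.40 to -0.22.

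The comparison of 30 µM with control asks what the lower dose did. Genes of fatty acid use were higher: ANGPTL4 rose 5.65-fold (2.50 ± 0.07, adjusted p = 1.62e-05), PDK4, which turns cells from glucose oxidation, 2.46-fold (1.30 ± 0.11), and CPT1A, the entry step of mitochondrial fatty acid oxidation, 2.44-fold (1.29 ± 0.12). The potassium channel genes KCNJ15 (1.22 ± 0.10) and KCNJ16 (0.95 ± 0.12), the galectin LGALS2 (1.20 ± 0.17), the proline dehydrogenase family member PRODH2 (1.18 ± 0.19) and dopa decarboxylase, DDC (1.06 ± 0.19), also rose. The largest falls were in NPPB (-1.54 ± 0.18), the glycine transporter SLC6A9 (-1.54 ± 0.19) and KRTAP2-3 (-1.07 ± 0.09), a keratin-associated gene with close paralogs. Falls also came in the leukotriene pathway gene ALOX5AP (-0.94 ± 0.09), AOX1 (-0.94 ± 0.10), TRPM2 (-0.84 ± 0.11) and the interleukin receptor IL7R (-0.77 ± 0.11). All 3 arrays at 30 µM lay beyond all 3 controls for each, as the rule for named genes required, with adjusted p of at most 0.0346. With normexp the log2 changes of dim genes shrank, to 0.29 for PRODH2, 0.39 for KCNJ15, -0.24 for SLC6A9, -0.24 for ALOX5AP, -0.23 for AOX1 and -0.21 for IL7R, while NPPB kept -1.43, KCNJ16 0.86 and KRTAP2-3 -0.69. PDK4 was at 0.71 and CPT1A at 0.69. As lower bounds, C7orf57 was at least 1.51-fold and MORN5 at least 1.48-fold higher, and ADAM9 at least 1.46-fold lower.

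At this dose 548 of 25568 genes passed (2.14%), 299 higher and 249 lower, and 18 changed at least 2-fold, 12 higher and 6 lower. The groups did not overlap in 25.8% of all genes, against 10% by chance, and 4565 genes had an unadjusted p under 0.05. Leaving out 1 array moved the count: to 139, 36 and 44 without control replicates 1, 2 and 3, to 34 and 46 without 30 µM replicates 1 and 2, and to 305 and 276 without 60 µM replicates 1 and 2. With the slide as a block, the same fit as without 60 µM replicate 3, 519 genes passed. With the slide row as a block 2 did, and the median standard error went from 0.09 to 0.11. That block compares 30 µM replicate 1 alone with the controls, and since this array also helped to call the 548 genes, their kept sign and size (104% for the median gene) add no independent support. Within the upper row of slide 1, limma on the 3 controls and the 30 µM array there, which is assumed to vary like the controls, called 0 genes, with 3346 at an unadjusted p under 0.05.

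PPAR targets and fatty acid oxidation had 6 of 17 genes up and 0 down at 30 µM (9 and 0 adjusted over the list alone). The median was 0.31 (adjusted p = 1.68e-07, and adjusted p = 0.0493 with an estimated correlation, the only list of the 28 to keep a call so in any of the 3 comparisons), or 0.09 with normexp. PLIN2 rose by 0.51 ± 0.06 there. Sterol genes were lower: of 24 in cholesterol synthesis and uptake 10 fell and 0 rose (18 and 0 adjusted over the list alone). The median was -0.26 (adjusted p = 6.53e-14, and adjusted p = 0.161 with an estimated correlation). Members included INSIG1 at -0.57 ± 0.07 and HMGCS1 at -0.33 ± 0.05. Fatty acid synthesis had 6 of 16 down and 0 up (10 and 0 adjusted over the list alone). The median was -0.21 (adjusted p = 7.44e-08, and adjusted p = 0.126 with an estimated correlation). Members included SREBF1 at -0.49 ± 0.05 and ELOVL6 at -0.41 ± 0.08, whereas SCD stood at -0.01 ± 0.07. ABCA1 fell (-0.59 ± 0.08).

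Stress and hypoxia lists were lower at 30 µM. ATF4 targets had 6 of 22 down and 0 up (10 and 0 adjusted over the list alone). The median was -0.22 (adjusted p = 7.44e-08, and adjusted p = 0.250 with an estimated correlation). Members included SLC7A5 at -0.74 ± 0.15, CHAC1 at -0.61 ± 0.09 and TRIB3 at -0.51 ± 0.09. For hypoxia and glycolysis 4 of 18 fell and 0 rose (13 and 0 adjusted over the list alone). The median was -0.33 (adjusted p = 1.00e-08, and adjusted p = 0.250 with an estimated correlation), ADM among them (-0.51 ± 0.09). Of 11 metallothionein list genes 3 fell and 0 rose (7 and 0 adjusted over the list alone). The median was -0.32 (adjusted p = 4.23e-06, and adjusted p = 0.250 with an estimated correlation). Heat shock genes had 1 of 14 down and 0 up (3 and 0 adjusted over the list alone). The median was -0.11 (adjusted p = 0.000347, and adjusted p = 0.276 with an estimated correlation). Immediate early genes had 1 of 14 down and 0 up (4 and 0 adjusted over the list alone). The median was -0.15 (adjusted p = 0.000704, and adjusted p = 0.250 with an estimated correlation).

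Higher at 30 µM were 3 more lists. Interferon-stimulated genes had 2 of 16 up and 0 down (3 up and 1 down adjusted over the list alone). The median was 0.15 (adjusted p = 0.00593, and adjusted p = 0.250 with an estimated correlation), or 0.06 with normexp. Proximal tubule differentiation genes had 1 of 11 up, SLC3A1 (0.45 ± 0.05), and 0 down (2 and 0 adjusted over the list alone). The median was 0.20 (adjusted p = 0.0212, and adjusted p = 0.276 with an estimated correlation, or adjusted p = 0.155 without control replicate 3), or 0.10 with normexp. The NRF2 list had 1 of 18 up and 0 down (2 and 0 adjusted over the list alone). The median was 0.06 (adjusted p = 0.0160, and adjusted p = 0.250 with an estimated correlation). It missed the threshold without control replicate 2 (adjusted p = 0.0656) and with the slide row as a block (adjusted p = 0.0645). The remaining lists did not pass at 30 µM, with adjusted p between 0.0565 and 0.765. Outside the lists that passed, CSF2 (0.56 ± 0.06) and GDF15 (0.82 ± 0.09) rose and IL6 (-0.41 ± 0.08), TAGLN (-0.44 ± 0.06) and PMAIP1 (-0.34 ± 0.06) fell. Of the 38 named genes that passed at 30 µM, 7 passed in all 9 fits that left out 1 array, ANGPTL4, PDK4, CPT1A, KCNJ15, KRTAP2-3 and ALOX5AP among them. The other 31 kept their sign and missed the threshold in at least 1. Some missed it in most: ADAM9 and ELOVL6 in 9, and SLC7A5, PMAIP1 and IL6 in 8. With the slide row as a block 37 of the 38, all but ANGPTL4, missed it.

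**Figure D3:**
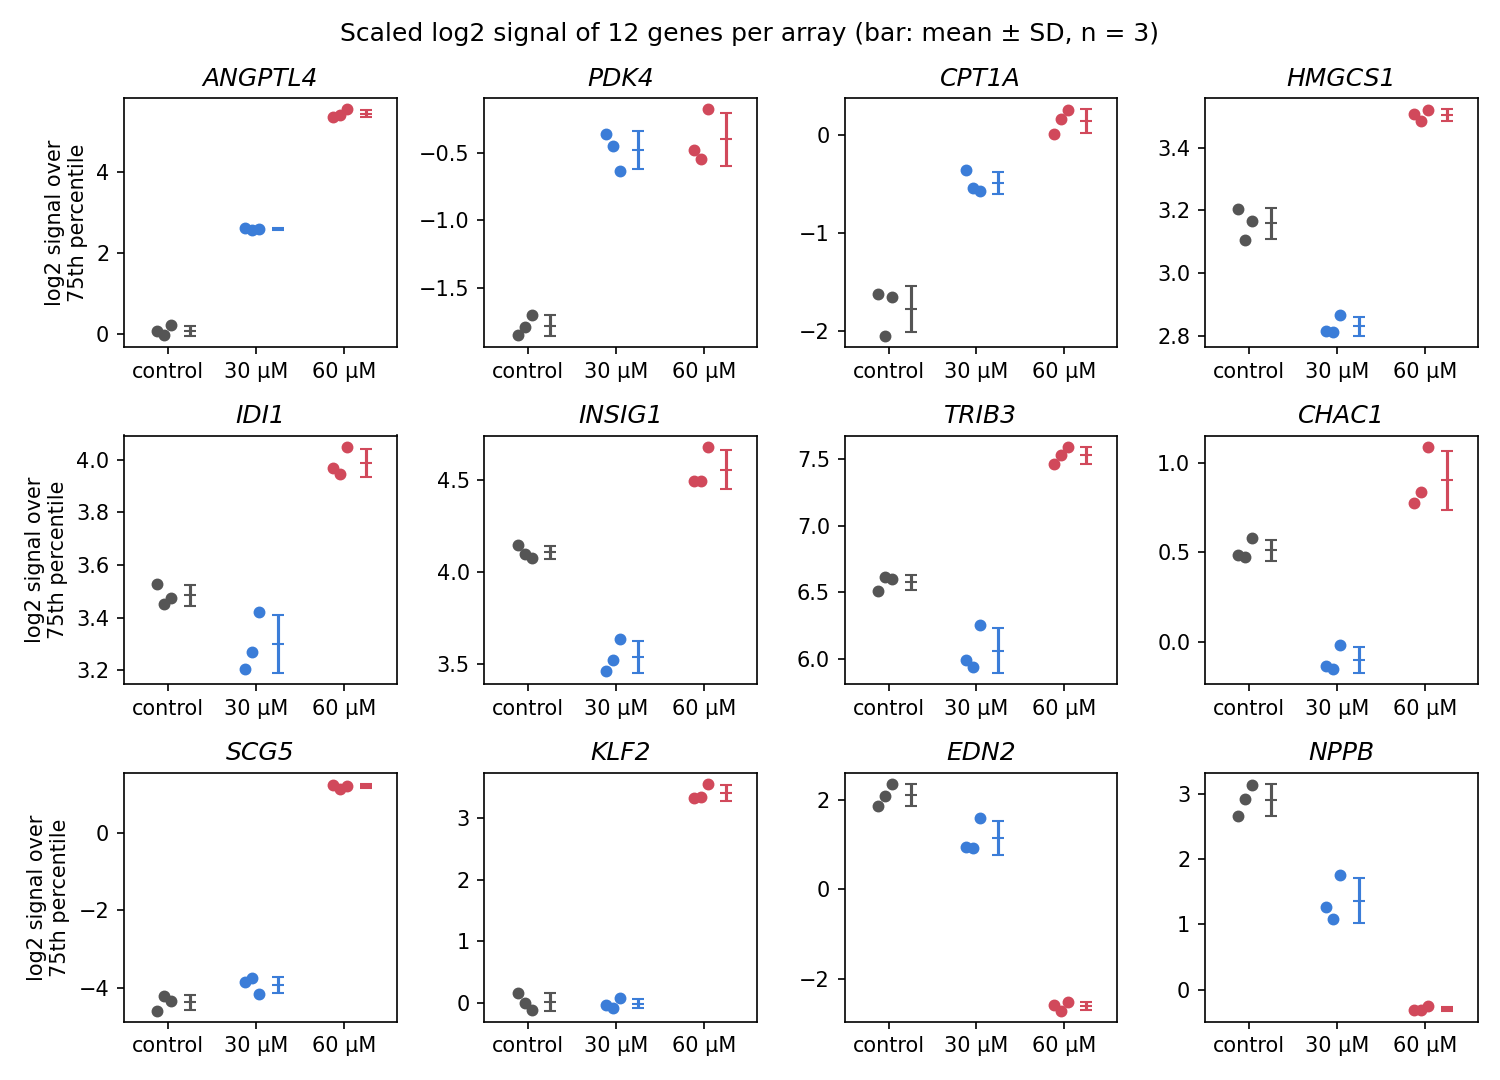
Scaled log2 signal (vertical axis, log2 units over the array's 75th percentile) of 12 genes in controls and at 30 and 60 µM, each point 1 array, with the mean ± SD of 3 arrays beside it. HMGCS1 has means of 3.16 in controls, 2.83 at 30 µM and 3.50 at 60 µM, and ANGPTL4 means of 0.09, 2.59 and 5.42.

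The comparison of 60 µM with 30 µM tests the difference between the doses. SCG5 was 35.4-fold higher at 60 µM (5.15 ± 0.13), SCEL 19.1-fold (4.26 ± 0.14) and TMEM158 17.1-fold (4.10 ± 0.07), followed by KLF2 (3.43 ± 0.09) and SHC4 (3.41 ± 0.11). SEMA5B (-4.20 ± 0.22), ANKRD2 (-3.79 ± 0.10), EDN2 (-3.74 ± 0.19), HOGA1 (-3.61 ± 0.05) and DHRS3 (-3.48 ± 0.15) were lower, in all 3 arrays against all 3, as the rule required. With normexp SCG5 was 5.64-fold and SCEL 6.05-fold higher, and the log2 differences were -1.68 for SEMA5B, -1.36 for ANKRD2, -2.31 for EDN2, -2.68 for HOGA1 and -1.94 for DHRS3. As bounds, SPINK1 was at least 10-fold and ASB5 at least 9.40-fold higher, and MYL3 at least 3.94-fold and CAVIN2 at least 3.92-fold lower. ANGPTL4 was 7.12-fold higher at 60 µM (2.83 ± 0.07), while PDK4 (0.08 ± 0.11, adjusted p = 0.624) and ALOX5AP (-0.03 ± 0.09, adjusted p = 0.845) showed no difference past the threshold. LGALS2 (-2.47 ± 0.17), DDC (-2.97 ± 0.19) and KCNJ16 (-1.56 ± 0.12), higher at 30 µM than in controls, were lower at 60 µM than at 30 µM, with normexp by -1.36, -0.97 and -1.41.

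Between the doses 9163 genes passed, 4335 higher and 4828 lower at 60 µM, 1185 of them at least 2-fold. With the slide as a block, the same fit as without 60 µM replicate 3, 8185 passed, and with the slide row as a block 6793. Within the lower row of slide 1, with 2 arrays per dose, 4185 did.

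Several lists moved from below the controls at 30 µM to above them at 60 µM, and the difference between the doses passed for each. Cholesterol synthesis had 17 of 24 genes higher at 60 µM and 2 lower (18 and 2 adjusted over the list alone). The median was 0.52 (adjusted p = 2.63e-07, and adjusted p = 0.210 with an estimated correlation), or 0.47 within the lower row of slide 1. ATF4 targets had 16 of 22 higher and 4 lower, also adjusted over the list alone. The median was 0.63 (adjusted p = 1.09e-05, and adjusted p = 0.254 with an estimated correlation). All but 1 of 18 hypoxia genes were higher, 17 and 0 lower, also adjusted over the list alone. The median was 1.28 (adjusted p = 4.98e-13, and adjusted p = 0.185 with an estimated correlation). Heat shock genes had 7 of 14 higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.25 (adjusted p = 0.000177, and adjusted p = 0.247 with an estimated correlation). Immediate early genes had 12 of 14 higher and 1 lower, also adjusted over the list alone. The median was 0.71 (adjusted p = 1.97e-06, and adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes went the other way, with 9 of 16 lower and 1 higher (11 and 1 adjusted over the list alone). The median was -0.48 (adjusted p = 0.000454, and adjusted p = 0.185 with an estimated correlation), or -0.19 with normexp.

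For fatty acid synthesis 10 of 16 genes were higher at 60 µM than at 30 µM and 0 lower, also adjusted over the list alone. The median was 0.35 (adjusted p = 0.000110, and adjusted p = 0.185 with an estimated correlation). The NRF2 list had 14 of 18 higher and 0 lower (14 and 1 adjusted over the list alone). The median was 0.41 (adjusted p = 5.21e-07, and adjusted p = 0.172 with an estimated correlation). ER chaperones had 9 of 20 higher and 1 lower (11 and 1 adjusted over the list alone). The median was 0.18 (adjusted p = 0.00863, and adjusted p = 0.247 with an estimated correlation). For autophagy and lysosome 11 of 23 were higher and 2 lower, also adjusted over the list alone. The median was 0.14 (adjusted p = 0.00200, and adjusted p = 0.185 with an estimated correlation). Phosphatidylcholine synthesis had 8 of 22 higher and 1 lower (9 and 2 adjusted over the list alone). The median was 0.10 (adjusted p = 0.0209, and adjusted p = 0.294 with an estimated correlation), or 0.04 with normexp. It was 0.045 without 60 µM replicate 3, and so with the slide as a block, which is the same fit. The call was lost with the slide row as a block (adjusted p = 0.0556).

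Lower at 60 µM than at 30 µM were 12 of 18 genes of TGF-beta response and matrix, with 4 higher, also adjusted over the list alone. The median was -0.40 (adjusted p = 0.00200, and adjusted p = 0.197 with an estimated correlation). Oxidative phosphorylation had 11 of 20 lower and 0 higher, also adjusted over the list alone. The median was -0.18 (adjusted p = 0.000454, and adjusted p = 0.254 with an estimated correlation). Of 18 ribosomal protein genes 5 were lower and 0 higher (1 and 0 adjusted over the list alone). The median was -0.13 (adjusted p = 0.00483, and adjusted p = 0.406 with an estimated correlation). Of 11 metallothionein list genes 5 were lower and 0 higher, also adjusted over the list alone. The median was -0.14 (adjusted p = 0.0248, and adjusted p = 0.496 with an estimated correlation), or -0.08 with the member that was dim at 60 µM at its bound. That call was lost without 30 µM replicate 3 (adjusted p = 0.144) and with probes above background on all 9 arrays (adjusted p = 0.0555). The remaining lists did not pass, with adjusted p between 0.277 and 0.847.

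The changes at both doses shared the controls, which alone gives a correlation across genes. It was r = 0.115 (Spearman's rho 0.152), against 0.5 in 100 simulated sets with no change, and genes are not independent replicates. The larger spread of the 60 µM changes (SD 0.46, against 0.20 at 30 µM) lowers r by itself. An r under 0.5 is thus no sign that the doses oppose each other. The covariance of the changes was 0.0105, against 0.00959 ± 0.000276 (SD) in the simulated sets. Both doses passed in 412 genes, 124 up in both, 98 down in both, 110 up at 30 µM and down at 60 µM, and 80 down and then up. Independent calls would give 47.7, 49.5, 59.4 and 39.7. Sharing the controls makes changes agree, so it can add to the first pair of counts and not to the second. Both tests also share each gene's estimate of spread, which can add to every one of these counts. An excess over independent calls thus does not by itself show that the doses agree or oppose each other. In the simulated sets, which held no change, 0 genes passed at both doses. The r was 0.176 without control replicate 2, 0.297 with no filter on dim probes and 0.331 with the slide row as a block. Shared arrays alone would give 0.6, 0.5 and 0.756 in these designs, so the values are not to be set against each other.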

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

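The tests of how the slide row bears on the gene lists, and the test on the 30 µM arrays of the lower row, were chosen only after the results were seen. The results here stand out because the effect of the lipid differed between the doses, for the lists by camera on the difference itself, and groups of 3 arrays are too small for a test of outlying samples. The median log2 difference between 60 µM and 30 µM was 1.28 for hypoxia and glycolysis, 0.71 for immediate early genes, 0.63 for ATF4 targets, 0.52 for cholesterol synthesis and uptake, 0.25 for heat shock genes and -0.48 for interferon-stimulated genes, lists that lay on opposite sides of the controls at the 2 doses. With normexp the interferon difference was -0.19. With an estimated correlation none of the 6 differences passed (adjusted p = 0.185 to 0.254). Among single genes, 190 passed at both doses in opposite directions, where independent calls would give 59.4 up and then down and 39.7 down and then up. Both tests share each gene's estimate of spread, which can raise the number found above that of independent calls. The count of 190 became 9 to 182 with 1 array left out and 0 with the slide row as a block. It was 345 with normexp at the 75th percentile and 454 with an intensity trend and robust spread. A count that moves so far carries little weight.

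The number of genes that changed at 60 µM could reflect the slide row, since all controls lay in 1 upper row. The tables argue against the row as the cause of most of these changes. The 30 µM arrays in the lower row, where 2 of the 60 µM arrays also lay, showed 6.42% and 3.90% of the 60 µM change from the controls, where a row effect needed at least 50%, unless the lower dose cancelled it. Between arrays of the same dose, those in the lower row differed from those in the upper row by -6.00% of the change at 60 µM and by 0.998% of it at 30 µM. That alone decides nothing, since each dose had 1 array in an upper row, at 60 µM on the other slide. The 10 splits of the 6 arrays are too few to judge chance: 1 of them, the real one, gave 9161 genes, and the others at most 0 by limma, with 494 to 885 at an unadjusted p under 0.05. Single genes with small changes stay open, since 2522 genes passed with the row as a block.

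The opposite shifts of the cholesterol, ATF4 and hypoxia lists at the 2 doses were set against the slide row and against a bias that follows signal. Within the lower row of slide 1 (2 arrays per dose), each of the 6 lists showed at least 89.9% of the difference between the doses. The arrays of the doses did not overlap there, so the difference does not need the row. Each dose also had 2 arrays in that row and 1 in an upper row, so the row could add little to it. The lists were picked on these same arrays, so the kept share adds no independent support. Whether the row shares in the shift of each dose from the controls stays open. With the row as a block at least 86.3% of the 30 µM shifts of the cholesterol, ATF4 and hypoxia lists remained, but that block rests on 30 µM replicate 1, the only treated array in the controls' row. Of 10000 random lists matched on signal, at most 0.03% had a median as far out, which argues against a bias that follows signal. For cholesterol genes at 60 µM 45.2% of the shift remained (0.08 against 0.18), by way of the same array, so the row may have raised that part. That the doses act differently on these lists is a hypothesis found and tested on the same data, and that the response turns over relative to the controls stays open.

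For the other counts, the real split of the arrays gave 548 genes at 30 µM and 9163 between the doses, in each case 1 of 10 splits, too few for a judgement. The others gave at most 0 by limma, with 706 to 1484 and 534 to 1434 genes at an unadjusted p under 0.05. Over all 3 groups, 1 of 100 drawn splits, the real one, gave as many as 9696 genes, the smallest share that 100 splits can give. This argues against a random grouping of these arrays. It says nothing of the slide row, and the replicates may be technical. The highest of the others gave 7609. The 5 others that kept the 60 µM arrays together gave 6953 to 7609 genes and the 94 that parted them at most 3, which points to the distance of the 60 µM arrays from the rest.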

How the results depend on the processing

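Normexp on the median signal, the slide row as a block and the fits within 1 slide row were chosen after seeing the data; the other alternatives were planned. There were 27 settings, of which the stricter threshold gave only counts. The slide block and leaving out 60 µM replicate 3, the same fit, were counted separately. Over the settings, 7176 of 7684 values of the 314 named gene results kept their direction and their side of the threshold. So did 1013 of 1066 values of the 40 list results, which also include fry and the estimated correlation. None of the list results reversed. Sizes moved more with normexp at the 75th percentile, whose offset compresses changes of dim genes: 38 of 134 named genes that passed at 60 µM, 12 of 38 at 30 µM and 33 of 127 between the doses fell under 50% of their log2 change, and the medians kept 86.7%, 77.7% and 86.5%. Of the 40 list medians 7 fell under 50% of their size in some setting, PPAR targets at 30 µM to 30.7% with this correction among them. The 60 µM counts and the count between the doses stayed within 1.5 times under each scaling, filter and probe rule tried. At an adjusted p under 0.01 they were 5565 and 6038, with 42 at 30 µM and 5934 over the 3 groups, because the threshold is stricter. The 30 µM count was 1014 with normexp, 1110 with normexp and quantile scaling, 1344 with an intensity trend and robust spread, 142 with no filter on dim probes and 93 with only the 2 groups compared. With no filter more genes are tested and with only the 2 groups fewer arrays measure the spread, and for the others the cause was not tested. Across genes as a whole, replicate numbers did not pair the arrays. Residuals of same-numbered arrays correlated at -0.197 to 0.177 over 9 pairs, and those of differently numbered arrays of different groups at -0.221 to 0.257. Of 9 arrays, 4 correlated best with an array of their own number. A correlation across genes cannot show whether single genes follow the replicate number, which was not tested gene by gene. With replicate numbers as a block the counts were 8375 at 60 µM, 154 at 30 µM, 8468 between the doses and 8530 over the 3 groups. With the slide row as a block they were 2522, 2, 6793 and 5493, and r between the doses 0.331, where shared arrays alone would give 0.756. The median passed gene kept its size, though on arrays that had helped to call it, and standard errors were larger. Single results did not all keep their size: the cholesterol list at 60 µM kept 45.2%. Within the lower row 4185 genes differed between the doses, on fewer arrays, and within the upper row limma called 0 at 30 µM, with 3346 at an unadjusted p under 0.05. The r was 0.297 with no filter, cause not tested. Camera with an estimated correlation called 0 lists at 60 µM, 1 at 30 µM and 0 between the doses, in place of 14, 11 and 15, and fry, which asks only whether a list's genes move, 22, 12 and 23.

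With each array left out in turn the counts ranged from 7233 to 9225 at 60 µM, 34 to 519 at 30 µM, 7667 to 8770 between the doses and 7826 to 9385 over the 3 groups, the lists called at 30 µM from 10 to 12, and r from 0.0811 to 0.176. The signs that reversed belong to changes near 0 that had not passed, and the cause was not tested. HAVCR1 at 30 µM was 0.0206 with normexp and quantile scaling and 0.0098 with quantile scaling, and SCD 0.0220 and 0.0223. SCD at 60 µM was -0.0645 with the slide row as a block. CXCL8 between the doses was 0.0033 when centred on detected probes, 0.0067 in the deposited table, 0.0540 with the slide as a block, and 0.11 with the slide row as a block and within the lower row, and PDK4 between the doses was -0.0321 with the slide as a block. Leaving out 1 array, SCD at 30 µM ranged from -0.0619 to 0.0477, CDKN1A at 30 µM from -0.10 to 0.0088, CXCL8 between the doses from -0.0725 to 0.0540 and PDK4 between the doses from -0.0321 to 0.15. Signal over background limits what was seen: 241 genes that passed at 60 µM were above background on no array of 1 group, so their folds are bounds.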

Other observations

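The gene families in this part were chosen after their values were seen, from 118 families of at least 15 tested genes that share a symbol stem. Pseudogenes and antisense, divergent and readthrough transcripts under these stems were then left out, also after the values were seen, which left 117 families. Of 15 Krüppel-like factors, transcription factors that act in growth and differentiation, 9 rose and 0 fell at 60 µM. The median was 0.35 (camera, adjusted over the 117 families, adjusted p = 0.00355, and adjusted p = 0.414 with an estimated correlation), or 0.22 to 0.36 over 5 scalings. KLF2, KLF4 and KLF6 also stand in the list of immediate early genes, and KLF13 (0.84), KLF9 (0.80), KLF10 (0.71) and KLF7 (0.65) rose outside it. Zinc finger genes had 127 of 448 down and 27 up at 60 µM, at a median of -0.11 (adjusted p = 0.0376, and adjusted p = 0.414 with an estimated correlation), or -0.11 to -0.05 over 5 scalings. At 30 µM the median was 0.04 (adjusted p = 0.00580, and adjusted p = 0.269 with an estimated correlation). Between the doses it was -0.14 (adjusted p = 0.000490, and adjusted p = 0.118 with an estimated correlation). Mitochondrial ribosomal proteins were lower at 60 µM. Of 49 genes for the large subunit 14 fell and 1 rose, at a median of -0.13 (adjusted p = 0.0239), and of 28 for the small subunit 9 fell and 1 rose, at a median of -0.13 (adjusted p = 0.0376), each with adjusted p = 0.780 with an estimated correlation.

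Intraflagellar transport genes, which build cilia, had 1 of 16 up and 0 down at 30 µM, at a median of 0.08 (adjusted p = 0.00539, and adjusted p = 0.269 with an estimated correlation). At 60 µM 8 of 16 fell and 0 rose (adjusted p = 0.0566). Between the doses 10 of 16 were lower at 60 µM and 0 higher, at a median of -0.31 (adjusted p = 0.00182, and adjusted p = 0.204 with an estimated correlation), or -0.31 to -0.20 over 5 scalings. IFT140, for example, was at 0.37 at 30 µM and -0.30 at 60 µM. In the estimated-correlation test 0 of the 117 families passed in any of the 3 comparisons.

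A candidate explanation for the higher hypoxia and glycolysis list at 60 µM is activity of hypoxia-inducible factor. Of 23 further targets of that factor outside the list, written down before they were tested, 21 rose and 0 fell at 60 µM, at a median of 0.63 (p = 5.93e-15, and p = 0.0113 with an estimated correlation). At 30 µM their median was -0.12 (p = 0.000124, and p = 0.127 with an estimated correlation). Oxygen and the factor itself were not measured, and other causes of the same target genes stay open.

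The higher PPAR list at 30 µM might reflect activation of PPAR receptors. Of 22 further targets 2 rose and 0 fell at 30 µM, at a median of 0.0205 (p = 0.0156, and p = 0.201 with an estimated correlation), which lies between the bounds set beforehand and decides nothing. Whether the proximal tubule list at 30 µM, higher by a median of 0.20 (0.10 with normexp), may be part of a broader tubule programme was tested on 18 further tubule genes. There 2 rose and 0 fell and 13 lay above 0, at a median of 0.15 (p = 6.06e-05, and p = 0.0738 with an estimated correlation), as that hypothesis needs. At 60 µM the same genes had 8 down and 1 up, at a median of -0.21 (p = 0.00912, and p = 0.209 with an estimated correlation).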
